A study of Aspergillus niger with 6 samples.

How the data were processed

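RNA was measured in mycelium of Aspergillus niger N402 from 6 shake flask cultures, 2 for each of 3 conditions. Per the labels' protocols, cultures grew at 28 °C in 100 ml of medium with 1% glucose or 1% ball-milled willow, and 1.5 g wet mycelium was transferred to willow after 48 h on glucose. Total RNA was depleted of ribosomal RNA with the Ribominus kit and made into SOLiD whole transcriptome libraries, which were read as 50 and 35 bp paired ends on a SOLiD 5500xl, per the labels' protocols. HTSeq is named in the submitters' processing notes, without a version. The aligner and its settings are not given in the sources used here. The libraries were grouped by the culture condition in the labels. The series' design text calls the cultures duplicates, so replicates A and B were taken as separate cultures of a condition.

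The deposited values of each library are counts, which are whole numbers of reads per gene, and RPKM values, both made by the authors, per the file headers. The header pairs gene models (Aspni5) with identifiers of a second strain, which begin with An. Of the 15431 genes listed, 14114 have an An identifier, and 14069 of these are in the reference table used for symbols and neighbours (RefSeq, assembly ASM285v2), which gives a symbol to 131. Because the builds differ, no coordinates are given. Another 5 entries per library hold reads that were not counted to any gene (outside genes, more than one gene, low quality, not aligned, multiply aligned). They were left out of library sizes and tests, and made up 96.9% to 98.5% of reads. The deposited RPKM values were found to be scaled by the authors to the sum over all entries, these included, since with that sum 100% of gene lengths came out whole within 0.01 bp (genes with over 20 counts), against at most 2.25% with the sum over genes. No count was found in any library for 3720 genes (24.1%). These include areA, argB and trpC, which growing mycelium uses, so that a count of 0 is given only as a value and not as absence of the transcript. Reads of near-identical genes may be among the multiply aligned ones, which HTSeq did not count to genes, so values of members of gene families are uncertain.

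Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with TMM factors and the default filter of filterByExpr (minimum count 10, minimum total 15), which kept 6181 genes and left out 9250. All 3 groups entered one fit with group means as the only terms and 3 residual degrees of freedom. Standard errors were computed as the log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size. Shares of reads have 95% Wilson intervals, and intervals and limits cover counting error only. The common biological coefficient of variation was 25.8%. Between the replicates of a condition the median gene differed 1.37-fold on glucose, 1.40-fold on willow and 1.37-fold after glucose addition, and a chi-square per degree of freedom of 6.81 to 11.5 put each pair beyond sampling noise. A gene without a count in one group is given as at least a ratio to 3 counts over both libraries of that group, and a gene with 1 to 3 counts as a ratio with an exact 95% counting interval.

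Gene lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01) where at least 5 members were tested, again with an estimated correlation, and with fry. The comparisons, tests, alternatives, the rule for named genes and 8 lists of 63 identifiers (cellulose, xylan, mannan with xyloglucan and galactose, pentose catabolism, starch and inulin, regulators, chitin and wall glucan, conidiation) were fixed before the data were examined. A further 5 lists (pectin, proteases, glycolysis, amino acid synthesis, secretion and folding) were made from the reference table's symbols before any test, but after the most abundant genes of each library had been seen. Of the identifiers fixed first, 28 have a symbol, and the planned check of members against product descriptions and 27 planned keyword patterns were not run because the table used holds no descriptions. Members without a symbol therefore stand under the list's name from their identifier alone. Genes named are, in the first and second comparison, the 10 largest increases and decreases among called genes with a mean RPKM of at least 50 in the higher group and no overlap between the groups, up to 4 called members per list (the largest changes), and, called or not, the regulators and a fixed set of genes for wall degradation and pentose use and glaA. This rule was also applied to the later lists, and other list members are named as examples chosen after their values were seen.

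The procedure was tested on simulated counts with known changes. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter. Counts were drawn with a dispersion that depended on abundance alone. The shares recovered and falsely called are therefore not those of the data. Of genes changed 2-fold, it recovered 8.60% for willow against glucose (5808 genes), 7.78% for glucose added against willow (5788 genes) and 12.6% for glucose added against glucose 48 h (5809 genes). Of those changed 4-fold it recovered 66.7%, 74.7% and 73.1%, and false calls made up 1.37%, 1.27% and 5.88% of calls. Alternatives were DESeq2 1.42.0, RLE, upper quartile and total-count scaling, other count filters, fits of the compared groups alone, the replicate letter as a block, the 10 most abundant genes left out, a minimum 2-fold change, and leaving out each library, in which the lone library of a group is assumed to vary like the other groups. The deposited RPKM values (limma-trend on log2(RPKM + 0.05)) and lists of members with a symbol were added after the data had been seen. Fold changes on that scale understate the change of low genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.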

Results

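Transcript abundance was measured by RNA sequencing in mycelium of Aspergillus niger N402, a laboratory strain of a filamentous fungus used in enzyme production. The 6 libraries covered 3 culture conditions, with 2 separate shake flask cultures (A and B) per condition. Mycelium was grown on glucose for 48 h, or was then washed and moved to ball-milled willow wood as its carbon source for 24 h. In the third condition, 24 h on willow were followed by 5 h with glucose. Reads assigned to genes numbered 635522 (A) and 758523 (B) on glucose, 557114 and 434508 on willow, and 775667 and 437314 after glucose addition. They made up between 1.46% (willow B, 95% Wilson interval 1.45% to 1.46%) and 3.15% (glucose added, A, 3.14% to 3.15%) of all reads of a library, while multiply aligned reads made up 58.4% to 75.7%. At this depth, 3 counts over both libraries of a group corresponded to 1.93 CPM (read counts scaled to the TMM-adjusted library size) on glucose, 3.66 CPM on willow and 2.42 CPM after glucose addition, and this level served as the limit for genes without a count. Limits and intervals of ratios cover counting error only.

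**Figure D1:**
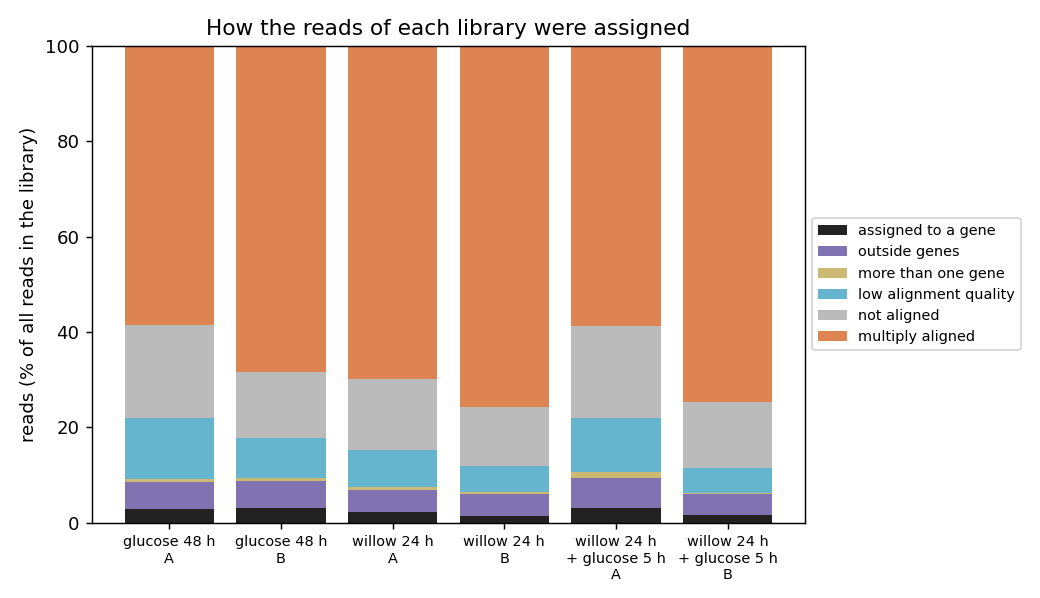
Assignment of the reads of each of the 6 libraries, as stacked bars in percent of all reads of the library. Reads assigned to a gene are the dark segments at the bottom, at most 3.15%, and multiply aligned reads are the largest segment, up to 75.7%.

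The first comparison asked which transcripts differed between mycelium kept on willow for 24 h and mycelium grown on glucose for 48 h. Carbon source, transfer and 24 h of further culture differed together between these conditions, so their effects cannot be told apart. Genes for enzymes that break down plant cell walls rose on willow to become some of the most abundant transcripts. The cellobiohydrolase genes cbhA and cbhB, whose products cut cellulose from the chain ends, went from 67.0 ± 24.9 and 21.7 ± 10.1 CPM on glucose (mean ± SD, n = 2, as for all CPM values given) to 23059 ± 5510.5 and 18029 ± 9137 CPM on willow. Transcripts of the endoglucanase gene eglB went from 18.3 ± 7.08 to 17420.2 ± 2233 CPM, and those of the xylanase gene xynB from 12.9 ± 12.5 to 9495 ± 3018 CPM. Among the genes that fell were the starch degradation gene aglU, from 7569.8 ± 1651 to 2323 ± 150.5 CPM, and the alcohol dehydrogenase gene adhA, from 6136 ± 161 to 1342 ± 116 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1089 of 6181 genes were higher and 836 lower on willow at an adjusted p under 0.05. Of these 1925 genes, 1877 had an estimated change of at least 2-fold. Few 2-fold changes passed the test in simulated counts, so this number depends on which changes the test can call.

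Of 13 tested genes of the cellulose degradation list, 10 rose and none fell (11 rose adjusted over the list alone), with a median log2 fold change of 8.42. The log2 fold changes ± SE were 9.89 ± 0.66 for eglB (edgeR adjusted p = 3.6e-11), 9.70 ± 0.69 for cbhB (adjusted p = 6.1e-11), 8.42 ± 0.73 for cbhA (adjusted p = 1.7e-09) and 9.41 ± 0.57 for the endoglucanase gene eglA (adjusted p = 1.5e-11). The cellulose list genes An12g02220 and An12g04610 reached 13159 ± 5103 and 14257 ± 2002 CPM on willow, from 11.3 ± 7.36 and 17.0 ± 6.97 CPM. Of 12 tested xylan degradation genes, 11 rose and none fell (12 rose adjusted over the list alone), with a median of 8.27. They included xynB at 9.46 ± 0.65 (edgeR adjusted p = 4.6e-11), aceA at 9.20 ± 0.65 (adjusted p = 6.0e-11), the alpha-glucuronidase gene aguA at 8.38 ± 0.59 (adjusted p = 5.4e-11) and the beta-xylosidase gene xlnD at 7.89 ± 0.51 (adjusted p = 2.6e-11). The feruloyl esterase gene faeA had no count in either glucose library and 834 ± 76.2 CPM on willow, at least 433-fold higher. Camera, which tests a list against all other genes, called both lists (Benjamini-Hochberg adjusted p = 1.6e-10 for cellulose and 1.5e-12 for xylan). Both calls held with an estimated correlation between genes, at adjusted p = 0.0457 for each.

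Genes for other wall polysaccharides and for pentose sugars also rose. Of 9 tested pectin degradation genes, 7 rose and none fell, with a median log2 fold change of 7.89, or 5.34 with the 3 genes without a count on glucose set to their bounds. The arabinanase gene abnA rose from 1 count over both glucose libraries to 651 ± 46.2 CPM, a ratio of 1007 with a 95% counting interval from 180.0 to 39849. The rhamnogalacturonan acetylesterase gene rgaeA, without a count on glucose, was at least 247-fold higher on willow. Of the genes of the mannan, xyloglucan and galactose list, 6 of 7 rose and none fell (7 rose adjusted over the list alone), with An01g01870 at 7.80 ± 0.53 (edgeR adjusted p = 4.1e-11) and the beta-mannosidase gene mndA at 2.76 ± 0.44 (adjusted p = 2.1e-05). On the deposited RPKM values the call of mndA was lost (1.48, limma-trend adjusted p = 0.109). Camera called the pectin list at adjusted p = 8.6e-06 and the mannan list at adjusted p = 5.0e-06. The pectin call was lost, at adjusted p = 0.0614 with an estimated correlation, and the mannan call held at adjusted p = 0.0457. All 4 pentose catabolism genes rose (also adjusted over the list alone), among them the D-xylose reductase gene xyrA at 7.92 ± 0.51 (edgeR adjusted p = 2.2e-11) and An07g03140 at 3.71 ± 0.39 (adjusted p = 5.4e-08).

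Among the regulators of carbon use, xlnR, which encodes the transcriptional activator of xylan and cellulose degradation genes, rose from 22.7 ± 10.7 to 285 ± 3.40 CPM (log2 fold change 3.63 ± 0.41, edgeR adjusted p = 1.3e-07). The carbon catabolite repressor gene creA rose from 35.0 ± 8.70 to 92.8 ± 1.88 CPM (1.40 ± 0.43, edgeR adjusted p = 0.0144). That call was lost with total-count scaling (0.97, adjusted p = 0.0815) and without glucose replicate A (1.13, adjusted p = 0.136). The gene amyR, which encodes the activator of starch degradation genes, fell from 79.0 ± 14.3 to 22.2 ± 11.8 CPM (-1.78 ± 0.56, edgeR adjusted p = 0.0171). It was not called without willow replicate B (-1.38, adjusted p = 0.0654) or with DESeq2 (adjusted p = 0.0503). The other 3 of 6 tested regulators, pacC among them, did not pass the test, the counts adjusted over the list alone were the same, and camera did not call the list (adjusted p = 0.504).

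Of 4 tested starch and inulin degradation genes, aglU fell (-1.70 ± 0.44, edgeR adjusted p = 0.00389) and the inulinase gene inu1 rose, with the same result adjusted over the list alone. The median of this list was -0.05 and its mean 0.44. Transcripts of inu1 had 1 count over both glucose libraries and 10.2 ± 5.17 CPM on willow, a ratio of 15.2 with a counting interval from 2.03 to 673 (edgeR adjusted p = 0.0271). Its call was lost without glucose replicate A (adjusted p = 0.149), willow replicate B (0.161) or glucose-added replicate A (0.0750), each of which left 1 called gene in the list, and with DESeq2 (adjusted p = 0.0694). The glucoamylase gene glaA had 38724 ± 7112 CPM on glucose and 22187 ± 376 CPM on willow (edgeR adjusted p = 0.259). In the glycolysis list, gpdA (-1.26 ± 0.37, edgeR adjusted p = 0.00973) and pkiA (-0.89 ± 0.33, adjusted p = 0.0415) fell, and the other 4 of 6 did not pass the test. Without glucose replicate B (gpdA -0.75, adjusted p = 0.167) or willow replicate A (-1.18, adjusted p = 0.0560) neither was called, and pkiA was called in none of the 6 fits that left out 1 library (adjusted p from 0.0508 to 0.211), nor by DESeq2 (adjusted p = 0.0651), with RLE scaling (0.0582) or in a fit of both groups alone (0.0634). Camera did not call glycolysis (adjusted p = 0.509).

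Of 7 tested protease genes, 4 rose and 1 fell, and camera did not call the list (adjusted p = 0.320). The aspergillopepsin gene pepA rose from 13.3 ± 5.18 to 1299 ± 718 CPM (6.58 ± 0.50, edgeR adjusted p = 1.9e-10). Fewer than 5 protease genes were called without glucose replicate A or without willow replicate B. DESeq2 called 4, and edgeR called 3 with at least 50 counts required in 2 libraries. One of the 5 was pepD (edgeR adjusted p = 0.0256), for which willow B was the only glucose or willow library with a count. Its call was lost without glucose A (adjusted p = 0.0768), glucose B (0.0828) or willow B, and with DESeq2 (0.261). Of 4 tested amino acid synthesis genes, leu2B rose (3.02 ± 0.44, edgeR adjusted p = 7.3e-06), while leu2A (-3.01 ± 0.44, adjusted p = 6.5e-06) and gdhA (-3.07 ± 0.44, adjusted p = 5.2e-06) fell. In the list for chitin and wall glucan, 2 of 3 genes rose (also adjusted over the list alone), with An02g07020 at 6.02 ± 0.46 (edgeR adjusted p = 2.2e-10). Of 5 tested secretion and folding genes, edgeR and DESeq2 each called 0, 2 had an unadjusted p under 0.05, and without either willow replicate edgeR called 1. It also called 1 with upper quartile scaling, without a count filter or with the replicate letter as a block, and 2 with total-count scaling, as did limma-trend on the deposited RPKM values (camera adjusted p = 0.509). Of 2 tested conidiation genes, which mark sporulating hyphae, An09g05730 rose (1.31 ± 0.35, edgeR adjusted p = 0.00560; also adjusted over the list alone). That call was lost with total-count scaling (0.88, edgeR adjusted p = 0.0529) and without glucose replicate A (1.16). Without a count filter, with more genes tested, 2 genes of the list were called, which need not be the 2 tested above. The number called also rose without willow replicate B.

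Outside the lists, the largest increases among the abundant genes named by rule were those of An01g11670 (10.23 ± 0.70, edgeR adjusted p = 4.6e-11), An09g00840 (10.11 ± 0.76, adjusted p = 1.5e-10) and An08g01760 (9.14 ± 0.55, adjusted p = 1.5e-11). The largest decreases included An01g14810, from 6606 ± 1167 to 11.9 ± 10.6 CPM, An01g14820, from 5602 ± 114 to 10.5 ± 8.66 CPM, and An13g01760, from 7906 ± 2683 to 18.1 ± 2.11 CPM. Higher genes made up 56.6% of calls with TMM and 35.2% with total-count scaling, which moved the median log2 fold change of all genes by -0.43 (upper quartile scaling by -0.12). On the deposited RPKM values, an alternative chosen after the data had been seen, the share was 19.4% and the shift -1.08. Besides mndA, limma-trend on these values did not call creA (0.26, adjusted p = 0.790), An09g05730 (0.17, 0.866), apsA (0.43, 0.662), pepD (adjusted p = 0.147) and inu1 (0.302), and it called glaA as lower on willow (-1.92, adjusted p = 0.0366) and 3 proteases. Requiring at least 50 counts in 2 libraries, with fewer genes tested, left 4 pectin, 3 protease and 1 starch and inulin gene called.

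**Figure D2:**
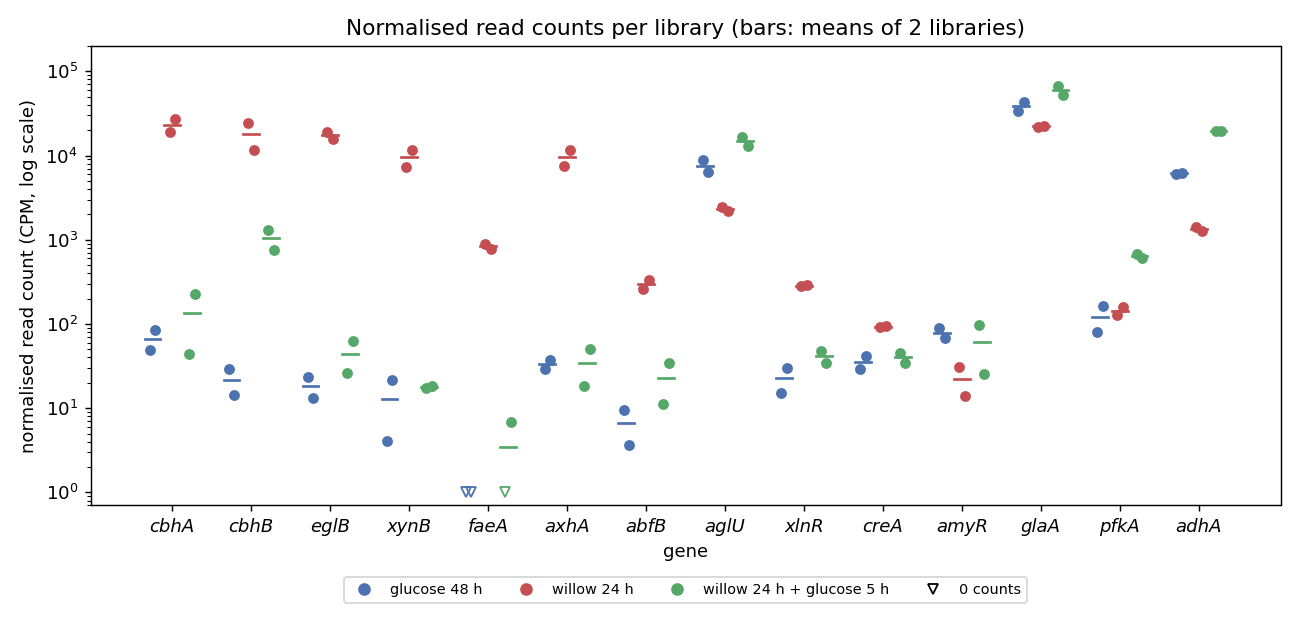
Normalised read counts (CPM, log axis) of 14 genes in each of the 6 libraries, where points are libraries, bars are means of the 2 libraries of a condition and open triangles are libraries with 0 counts. Transcripts of cbhA, for example, had a mean of 67.0 CPM on glucose, 23059 on willow and 134 after glucose addition.

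The second comparison set cultures on willow that had been given glucose for 5 h against separate cultures on willow and asked which transcripts differed. No culture was kept on willow for those 5 h without glucose, so added glucose and 5 h of further culture cannot be told apart. Transcripts of xynB fell from 9495 ± 3018 to 17.9 ± 0.855 CPM, those of aceA from 9662 ± 6111 to 10.7 ± 1.19 CPM, and those of eglB from 17420.2 ± 2233 to 44.2 ± 25.8 CPM. In the other direction, adhA rose from 1342 ± 116 to 19571 ± 77.5 CPM, aglU from 2323 ± 150.5 to 14895 ± 2657 CPM and the phosphofructokinase gene pfkA from 143 ± 24.2 to 635 ± 50.7 CPM. Of 6181 genes, 1066 were higher and 1270 lower after glucose addition (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without glucose-added replicate A, 1496 genes were called instead of 2336.

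All 12 tested xylan degradation genes fell, as did 10 of 13 cellulose degradation genes, 7 of 9 pectin degradation genes and all 4 pentose catabolism genes, and none in these lists rose. Adjusted over the list alone, 12 xylan, 11 cellulose and 4 pentose genes fell. Median log2 fold changes were -7.49 for xylan, -5.09 for cellulose, -5.63 for pectin and -4.12 for pentose genes. Single values were -9.81 ± 0.69 for aceA (edgeR adjusted p = 1.8e-10), -9.04 ± 0.64 for xynB (adjusted p = 1.8e-10), -7.47 ± 0.70 for cbhA (adjusted p = 1.2e-08), -4.12 ± 0.52 for cbhB (adjusted p = 1.3e-06) and -7.36 ± 0.50 for xyrA (adjusted p = 1.7e-10). Of the mannan, xyloglucan and galactose list, 6 of 7 genes fell and 1 rose (also adjusted over the list alone). The riser was the alpha-galactosidase gene aglC (1.79 ± 0.37, edgeR adjusted p = 5.5e-04), whereas its relatives aglA (-1.60 ± 0.35, adjusted p = 8.9e-04) and aglB (-3.20 ± 0.41, adjusted p = 1.2e-06) fell. Camera gave adjusted p = 2.5e-11 for xylan, 1.8e-09 for cellulose, 2.4e-06 for pectin and 0.00155 for mannan. None of these calls held, at adjusted p = 0.0688 with an estimated correlation for the first 3 lists and adjusted p = 0.0811 for mannan.

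Of 6 glycolysis genes, 3 rose after glucose addition and none fell. The risers were pfkA (2.15 ± 0.37, edgeR adjusted p = 7.2e-05), the glyceraldehyde-3-phosphate dehydrogenase gene gpdA (1.48 ± 0.37, adjusted p = 0.00290) and the pyruvate kinase gene pkiA (1.41 ± 0.33, adjusted p = 0.00166). Camera called glycolysis at adjusted p = 0.0380, and lost it at adjusted p = 0.165 with an estimated correlation and at adjusted p = 0.0558 without willow replicate B. Of 4 starch and inulin degradation genes, 3 rose (also adjusted over the list alone), with aglU at 2.68 ± 0.45 (edgeR adjusted p = 6.0e-05) and glaA at 1.42 ± 0.52 (adjusted p = 0.0353). Transcripts of glaA went from 22187 ± 376 to 59386 ± 10135 CPM. Its call was lost without willow replicate A (adjusted p = 0.0924), willow replicate B (0.0695) or glucose-added replicate A (0.0991), and with at least 50 counts required in 2 libraries (0.0674). The third riser was inu1 (edgeR adjusted p = 0.0431), whose call was lost without willow A (adjusted p = 0.256), glucose-added A (0.349) or glucose-added B (0.0785), with DESeq2 (0.143) and with the replicate letter as a block (0.0611). Without willow A or glucose-added A the list had 1 call.

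Transcripts of xlnR fell from 285 ± 3.40 to 41.4 ± 9.53 CPM (-2.75 ± 0.39, edgeR adjusted p = 6.0e-06). Those of creA fell (-1.18 ± 0.43, adjusted p = 0.0348), a call lost without willow A (0.0843), willow B (0.0851), glucose-added A (0.0936) or glucose-added B (0.168), with total-count (0.114) or upper quartile scaling (0.0552), without a count filter (0.0813), and with DESeq2 (0.0770). Those of amyR rose (1.50 ± 0.57, edgeR adjusted p = 0.0422), with 0.20 (adjusted p = 0.867) without glucose-added A and 1.09 (adjusted p = 0.151) without willow B, and DESeq2 did not call it (adjusted p = 0.115). Nor did edgeR with at least 50 counts required in 2 libraries (adjusted p = 0.0848) or in a fit of both groups alone (0.0679). Without glucose-added A or willow B, and with DESeq2, 1 regulator was called instead of 3. The other 3 regulators did not pass the test, counts adjusted over the list alone were the same, and camera did not call the list (adjusted p = 0.717), whose median was 0.15 and mean -0.22.

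The protease genes pepA (-3.07 ± 0.40, edgeR adjusted p = 1.9e-06) and apsA (-1.91 ± 0.45, adjusted p = 0.00178) fell, and the other 5 of 7 did not pass the test (camera adjusted p = 0.332). On the deposited RPKM values apsA was not called (-1.16, limma-trend adjusted p = 0.275). Of the amino acid synthesis genes, leu2A (1.84 ± 0.45, edgeR adjusted p = 0.00244) and gdhA (1.82 ± 0.43, adjusted p = 0.00170) rose and leu2B (-3.83 ± 0.49, adjusted p = 1.5e-06) fell, so that the list's median was 0.52 and its mean -0.24. The call of leu2A was lost without glucose-added A (1.47, adjusted p = 0.0520), and gdhA had 2.90 without willow A. In the chitin and wall glucan list 2 of 3 genes fell (also adjusted over the list alone), with An02g07020 at -4.63 ± 0.43 (edgeR adjusted p = 1.0e-08). Of the secretion and folding genes, edgeR and DESeq2 called 0 and 2 had an unadjusted p under 0.05, while edgeR called 1 without any 1 of the glucose or willow libraries, 1 with upper quartile scaling or the replicate letter as a block, and 4 with total-count scaling (camera adjusted p = 0.332). Of the conidiation genes, edgeR and DESeq2 called 0 (also adjusted over the list alone), and 0 had an unadjusted p under 0.05.

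Outside the lists, the largest increases among the abundant genes named by rule were those of An02g06820, from 243 ± 1.33 to 7521 ± 178 CPM (4.95 ± 0.49, edgeR adjusted p = 2.9e-08), An15g02040, from 213 ± 98.0 to 5112 ± 1404 CPM (4.59 ± 0.46, adjusted p = 3.2e-08), and An08g05640, from 1008 ± 510.4 to 18605 ± 268 CPM (4.20 ± 0.52, adjusted p = 9.8e-07). Higher genes made up 45.6% of calls with TMM and 59.9% with total-count scaling, which moved the median log2 fold change by 0.30 (upper quartile scaling by 0.12). On the deposited RPKM values the share was 66.3% and the shift 0.56. Besides apsA, limma-trend on these values did not call creA (-0.54, adjusted p = 0.642), amyR (1.61, 0.0954), mndA (-1.14, 0.284) and TID_42743 (-1.36, 0.0664), of which edgeR had called mndA at -1.84 (adjusted p = 0.00139) and TID_42743 at -2.08 (0.00560). The call of TID_42743 was also lost without willow A (edgeR adjusted p = 0.0997) or glucose-added A (0.170). Requiring at least 50 counts in 2 libraries left 4 pectin genes and 1 gene each of the protease, starch and regulator lists called.

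How far the changes seen on willow were reversed after glucose addition was read from the overlap of both sets of calls. Without a culture kept on willow for the same 5 h, a reversal cannot be credited to glucose alone. Of the 1089 genes higher on willow, 801 (73.6%) were lower after glucose addition. They included the xylan degradation genes that rose on willow and those of the cellulose list except An14g01770 (log2 fold change -1.68, edgeR adjusted p = 0.0830), a gene named after its value was seen. Of the 836 genes lower on willow, 487 (58.3%) were higher after glucose addition. Independent lists of these sizes would share 224 and 144 genes, and 20 simulations of unchanged groups sharing the willow libraries gave an overlap of at most 0. Unchanged groups give almost no calls (at most 1 gene higher on willow, or lower after glucose, per simulation), so that simulated overlap says nothing about lists of called genes. Across genes, which are not independent replicates, the fold changes of both comparisons had a Pearson r of -0.76 (simulated -0.56) and a covariance of -3.29 (simulated -0.15, a difference of -3.14). The 2 willow libraries are too few to leave 2 for each comparison, so part of the excess may come from the shared libraries.

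**Figure D3:**
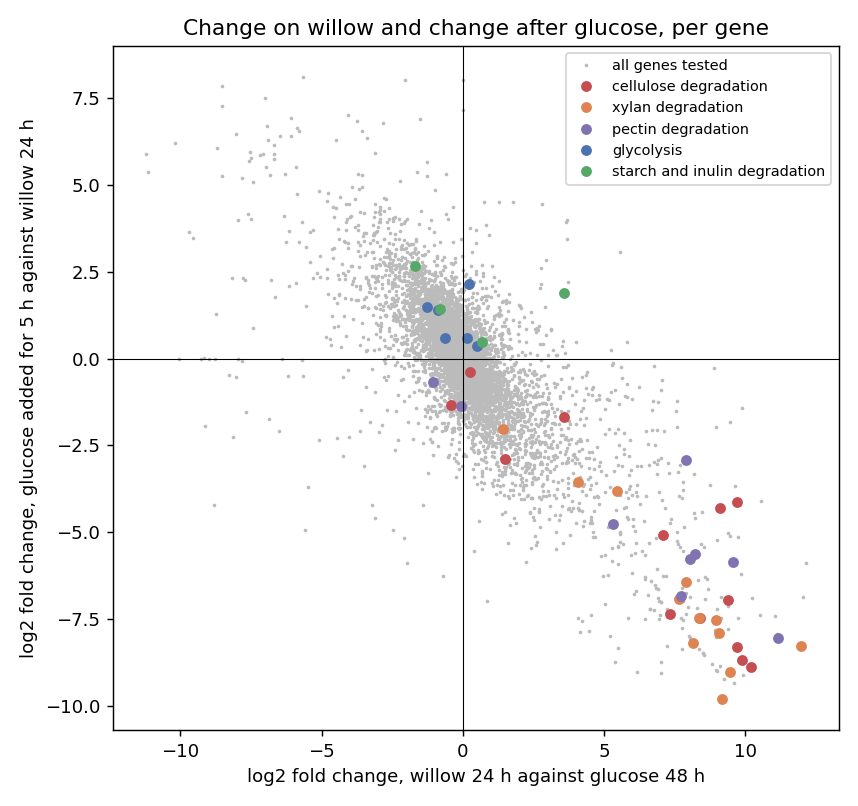
Log2 fold change of each of the 6181 tested genes on willow against glucose 48 h (horizontal axis) and after glucose addition against willow (vertical axis), with members of 5 gene lists in colour. Xylan and cellulose degradation genes lie at the lower right, with medians of 8.27 and 8.42 on willow and -7.49 and -5.09 after glucose addition, and the position of genes without a count in a group depends on the prior count.

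The third comparison set cultures with glucose added for 5 h against cultures on glucose for 48 h and asked which transcripts differed. The transfer, 24 h on willow, 5 h of further culture and the time since glucose was supplied differed together between these conditions. Their effects cannot be told apart. Transcripts of cbhB were at 1036 ± 405 CPM against 21.7 ± 10.1 CPM on glucose (5.58 ± 0.60, edgeR adjusted p = 2.8e-07). Also higher were An01g01870 (4.26 ± 0.46, adjusted p = 3.6e-07), lacA+ (2.77 ± 0.44, adjusted p = 6.5e-05) and eglA (2.46 ± 0.52, adjusted p = 0.00126). In contrast, eglB (44.2 ± 25.8 CPM, edgeR adjusted p = 0.162) and xynB (17.9 ± 0.855 CPM, adjusted p = 0.737) did not pass the test, nor did cbhA (0.95 ± 0.58, adjusted p = 0.291), which passed it without glucose-added A (1.74, adjusted p = 0.0450). Transcripts of pfkA (2.38 ± 0.36, edgeR adjusted p = 4.1e-05), aglC (2.78 ± 0.38, adjusted p = 8.1e-06) and adhA (1.67 ± 0.43, adjusted p = 0.00767) were higher than on glucose for 48 h. In all, 619 genes were higher and 548 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Instead of 1167 genes, 722 were called without glucose B, 631 without glucose-added A and 776 without glucose-added B.

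Of the cellulose degradation genes, 4 of 13 were higher than on glucose for 48 h (5 higher and 1 lower adjusted over the list alone), and 7 were called without glucose A. Of the mannan, xyloglucan and galactose genes, 3 of 7 were higher (also adjusted over the list alone). Camera called both lists, each at adjusted p = 0.0150. Neither call held, at adjusted p = 0.336 with an estimated correlation for both, nor without glucose A (adjusted p = 0.0622 and 0.0670), and that of cellulose was lost without glucose-added B (adjusted p = 0.0956). Of 12 xylan degradation genes, edgeR and DESeq2 called 0 (edgeR also 0 adjusted over the list alone), 3 had an unadjusted p under 0.05, and edgeR called 2 without glucose-added A and 1 without any 1 of glucose A, glucose B, willow A or willow B. With the replicate letter as a block it called 1, xlnD (1.56, adjusted p = 0.0451, against 1.46 and 0.0766 without the block). Camera gave adjusted p = 0.0935 for xylan, which passed without glucose B (0.0291) and without glucose-added A (0.0287). For pectin degradation, edgeR called 3 of 9 genes and DESeq2 0, and edgeR called 1 without glucose B or either glucose-added library, and in a fit of both groups alone, as did limma-trend on the deposited RPKM values (camera adjusted p = 0.433). The 3 pectin genes called by edgeR were higher, and adjusted over the list alone 3 were higher and 2 lower. The median log2 fold change of the list was 2.27, or 0.58 with 3 genes at their bounds.

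In the glycolysis list, pfkA was the 1 called gene of 6 (camera adjusted p = 0.0935, and 0.0291 without glucose B), and 2 were called with the replicate letter as a block. Of the proteases, 3 were higher and 1 lower, with pepA at 3.51 ± 0.48 (edgeR adjusted p = 1.0e-05) and pepE at -1.48 ± 0.36 (adjusted p = 0.00488), but 1 gene was called without glucose-added B. The median of the proteases was -0.33, while their mean was 1.22 and camera pointed up (adjusted p = 0.605). That mean includes pepD at 6.29, a gene without a count on glucose and one of the 3 called higher (edgeR adjusted p = 0.0150). Its call was lost with DESeq2 (adjusted p = 0.280), without glucose A (6.27) and without glucose B (6.22). Starch and inulin degradation had 2 of 4 genes higher (3 adjusted over the list alone) and 1 without glucose B or glucose-added A, with at least 50 counts required in 2 libraries or on the deposited RPKM values. In the chitin and wall glucan list An02g07020 was called (1.38 ± 0.43, edgeR adjusted p = 0.0239; also adjusted over the list alone), but not without glucose A (0.0725) or glucose-added B (0.72, adjusted p = 0.418). The lower amino acid synthesis genes leu2A (-1.16 ± 0.36, edgeR adjusted p = 0.0256) and gdhA (-1.25 ± 0.40, adjusted p = 0.0303) both lost their call without glucose-added B (0.236 and 0.229). The call of leu2A was also lost without glucose A (0.226) and with DESeq2 (0.0858), and that of gdhA without glucose B (0.0877) or glucose-added A (0.0675). No gene was called by edgeR or DESeq2 among pentose catabolism (0 with an unadjusted p under 0.05), regulators (0; camera adjusted p = 0.520), conidiation (1) and secretion and folding genes (1; camera adjusted p = 0.678), nor adjusted over the list alone. Without glucose A, edgeR called 1 regulator and 1 conidiation gene. The secretion list had a median of -0.07 and a mean of 0.14.

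Of the 801 genes that rose on willow and fell after glucose addition, 648 were not called against glucose 48 h, 108 were higher and 45 lower. Of the genes lower on willow, 266 were also lower after glucose addition than on glucose for 48 h, and of those higher on willow 258 were also higher, where independent lists would share 74.1 and 109. Part of the excess may come from the glucose libraries that both comparisons share. Against willow, 65 of the lower genes were higher after glucose addition, 27 were lower and 174 were not called, and of the higher genes 108 were lower, 17 were higher and 133 were not called. Among the lower genes were An01g14810 with 13.4 ± 13.7 CPM after glucose addition against 6606 ± 1167 CPM on glucose for 48 h (-9.16 ± 0.67, edgeR adjusted p = 5.1e-10), An13g01760 with 45.7 ± 10.5 against 7906 ± 2683 CPM (-7.45 ± 0.52, adjusted p = 3.2e-10), and TID_124807, which had 1741 ± 1029 CPM on glucose and no count after glucose addition, at least 721-fold lower. A further 233 genes, not called between willow and glucose 48 h, were higher after glucose addition than in both other conditions. They included pfkA and TID_37149, which had 115 ± 23.9 CPM on glucose, 189 ± 11.2 CPM on willow and 1036 ± 330.0 CPM after glucose addition. Higher genes made up 53.0% of calls with TMM and 27.6% on the deposited RPKM values, with a shift of the median of -0.53 (total-count scaling -0.14). Limma-trend on the RPKM values did not call adhA (1.12, adjusted p = 0.354), leu2A (-1.72, 0.0634), An02g07020 (0.73, 0.508), An08g01760 (1.04, 0.336), An02g06820 (0.94, 0.365), An15g02040 (1.30, 0.254), An16g07080 (1.04, 0.306) and abnA (adjusted p = 0.192), all called by edgeR with the counts of all libraries. Of these, edgeR also lost An08g01760 with total-count (adjusted p = 0.0698) or upper quartile scaling (0.0509), in a fit of both groups alone (0.0694) and without glucose B (0.319), glucose-added A (0.0794) or glucose-added B (0.263). It lost An02g06820 without glucose A (adjusted p = 0.168), glucose-added A (0.0735) or glucose-added B (0.0580), An16g07080 without glucose-added B (0.120) and abnA without glucose-added A (0.173), and DESeq2 did not call abnA (0.0519).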

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

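No test was chosen for this part after the values were seen. Reads that align to more than one place are outside the gene counts compared above, and their share was higher in both willow libraries than in both libraries from glucose for 48 h. It was 69.8% in willow A and 75.7% in willow B, against 58.4% and 68.3% on glucose. With added glucose, A (58.8%) lay between the glucose libraries and B (74.8%) between the willow libraries, and in all 3 conditions the share was higher in B than in A. The 95% Wilson intervals of the willow shares were 69.82% to 69.85% and 75.70% to 75.73% and cover counting error only. The difference between conditions was not tested, and which sequences these reads came from was not analysed here.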

How the results depend on the processing

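The tests on the deposited RPKM values, rescaled or not, and on list members with a symbol were chosen after the data had been seen, and all other alternatives before. Higher and lower calls together stayed within 1.5 times of those given for each comparison under RLE, upper quartile and total-count scaling and with DESeq2. They also did so without a count filter, in fits of the compared groups alone, without the 10 most abundant genes and with a minimum 2-fold change. The last is a weak check, because few genes with a smaller estimated change were called. The split by direction did change with total-count scaling, where 834 genes were higher and 1532 lower on willow, against 1089 and 836 with TMM. Of those 2366 calls, 1670 were shared with the TMM fit. Requiring at least 50 counts in 2 libraries left 1056 calls for willow against glucose, 1297 for glucose added against willow, 769 for glucose added against glucose 48 h and 441 genes higher on willow and lower after glucose, with fewer genes tested (2743). The deposited RPKM values gave 714 calls for glucose added against glucose 48 h and 327 reversing genes. Rescaled to gene totals they gave 872 and 550, and with TMM factors as well 802 and 707, so both choices account for part of the difference in reversing genes, and the cause of the rest was not tested. DESeq2 called 1540, 1801 and 830 genes. Leaving out each library gave 1618 to 2037, 1496 to 2501 and 631 to 1439 calls in the order of the comparisons, and 612 to 745 reversing genes.

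Of the lists, 4, 5 and 2 were called by camera in these comparisons. An estimated correlation left 3, 0 and 0. The fry test, which does not compare a list with other genes, called 6, 8 and 3. Beyond the lists camera called, these were regulators and proteases in the first comparison and glycolysis in the third. In the second they were regulators, proteases, and secretion and folding. Members with a symbol left 1 list called by camera for glucose added against glucose 48 h. Leaving out each library gave 4 in each fit, 4 to 5 and 0 to 4 called lists, and the cause was not tested. The letter was not taken to pair the libraries, because the labels do not say that A and B mark a shared batch. The deviations of replicates A and B from their condition means had correlations of -0.0137, 0.120 and 0.167 between conditions. In all 3 conditions B nevertheless had a lower share of unaligned reads than A (12.3% to 13.9% against 14.9% to 19.7%) and of low-quality reads (5.28% to 8.43% against 7.86% to 12.7%), so a batch that goes with the letter is not excluded. With the letter as a block, 2004, 2432 and 1292 genes, 836 reversing genes and 4, 5 and 2 lists were called. Named genes were compared only in alternatives that still tested them, and the minimum 2-fold change was not applied to them. A gene that a filter left out is therefore not counted as a lost call. Among the combinations of gene, comparison and alternative compared, calls of named genes were lost in 103 and gained in 30. In 3216 the outcome was the same, and no called named gene changed sign. Counts on the other strand were not run, because the values used here hold no such column. At this depth few 2-fold changes passed the test in simulated counts, where far fewer genes changed than were called here. That share is not the recovery in these comparisons, but a gene not called may still have changed.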

Other observations

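The tests of the gene share of reads, of rescaled RPKM values, of split glucose libraries and of chance placement of neighbours were chosen after the results were seen, as were the runs of genes named here. Several genes that changed on willow lie beside each other in the reference table (assembly ASM285v2). From An03g03520 to An03g03560, 5 neighbours were lower than on glucose for 48 h both on willow and after glucose addition. An03g03530, for example, had 685 ± 17.1 CPM on glucose, 2.47 ± 0.418 CPM on willow and 1.77 ± 0.762 CPM after glucose addition (mean ± SD, n = 2). From An12g03750 to An12g03780, 4 neighbours were also lower than on glucose for 48 h in both other conditions, among them An12g03760 with 7448 ± 3069.5, 655 ± 209 and 78.1 ± 30.1 CPM. From An06g02110 to An06g02150, 5 neighbours rose, with An06g02130 at no count on glucose and 304 ± 59.9 CPM on willow. The run from An07g08910 to An07g08950 ends with eglB, next to An07g08940 at 3.02 ± 4.27 CPM on glucose and 1761 ± 135 CPM on willow. From An18g02680 to An18g02730, 6 neighbours rose and were also higher after glucose addition than on glucose for 48 h, with An18g02700 at 33.1 ± 21.1, 678 ± 38.7 and 373 ± 86.6 CPM (edgeR adjusted p = 1.4e-06 against glucose 48 h).

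In all, 161 of 2955 neighbouring pairs were higher on willow in both members, whereas chance placement in 2000 shuffles of the gene positions gave 91.8 on average and at most 123. Reads of a strongly expressed gene counted on its weaker neighbour are a candidate explanation. Of the pairs, 138 had a weaker member with at least 10% of the stronger one's level, against at most 102 in the shuffles. That argues against it as the whole cause only if such reads stay below 10% of the stronger gene's level, which was not tested. Pairs lower on willow numbered 105 (at most 75 in the shuffles). Tandem copies of one gene and control shared by neighbours stay open and were not tested.

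The 266 genes lower on willow and lower after glucose addition than on glucose for 48 h, An01g14810 and An13g01760 among them, exceed the 74.1 that independent lists would share. Part of the excess may come from chance-high values in the shared glucose 48 h libraries, but with 1 glucose library as control of each comparison, assumed to vary like the other groups, 187 and 177 genes were lower in both, against 52.2 and 35.0 in independent lists, which argues against them as the whole cause. With RLE, upper quartile and total-count scaling there were 252 to 373 such genes, but this cannot decide whether scaling was the cause. Total-count scaling moved the median fold changes against glucose down, by -0.43 on willow and -0.14 after glucose addition (log2), which favours such genes. Upper quartile scaling moved the median on willow by -0.12 and that after glucose addition by only -0.0046. RLE moved these medians by only 0.057 on willow and 0.017 after glucose addition (log2). One library alone was tested by the share of these genes among all genes lower after glucose. It was 48.5% with all libraries and at least 37.7% with 1 left out. A glucose or glucose-added library behind the pattern would lower both counts together, so this share cannot decide the question. The count itself fell most without glucose-added A and without glucose B. Of these genes 65 were higher after glucose addition than on willow, 27 lower and 174 not called, and a return that takes longer than 5 h stays open as a hypothesis that no value here decides, as do culture age and the transfer of mycelium, which were not tested.

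The share of higher genes among calls on willow was 19.4% with the deposited RPKM values and 56.6% with counts and TMM. Division of RPKM by all reads of a library, most of them not counted to a gene, may account for part of this. Rescaling to gene totals alone brought the share to 36.0%, and TMM factors alone to 32.2%. With both changes the share was 55.1%, so neither alone accounts for the whole difference. Whether mycelium on willow held less messenger RNA per total RNA cannot be decided from the gene share of reads. The RNA had been depleted of ribosomal RNA, and multiply aligned reads were not counted to genes, so the share does not measure it. The mean gene share of reads was 1.58 times as high on glucose for 48 h as on willow, while replicates of 1 condition differed up to 1.98 times. That largest difference was in the glucose-added pair (3.15% and 1.59%). The shares were 2.97% and 2.99% on glucose and 2.32% and 1.46% on willow.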
